A study of Mus musculus with 7 samples.

How the data were processed

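Peak lists of H3K4me1 ChIP-seq from 1 WT and 1 Lsh KO sample of primary mouse embryonic fibroblasts were analysed. Per the labels' protocols, cross-linked chromatin was sonicated to 200 to 300 bp, precipitated with an antibody to H3K4me1 and sequenced on an Illumina Genome Analyzer IIx, with an input library for each genotype. Partek and the mouse build mm9 are named in the submitters' processing notes. The aligner, the version of Partek and its settings are not given in the sources used here. Per the file headers, the p-value of each peak sets the ChIP library against the input of the same genotype, and each list names a single ChIP library.

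The deposited columns held counts of ChIP and input reads in each peak and the count of extended reads in the highest window. They also held that window count as RPM, scaled by the size of the ChIP library, per the file headers. The authors' p-value of each peak equalled, where above 1e-30 and within 1e-05 on the log10 scale, the upper tail of a binomial test of its ChIP reads among its ChIP and input reads, with the library sizes setting the expected share. The largest deposited p-value of a list was 1.10e-05 for WT and 1.34e-05 for KO. The value was written as 0 for 6883 WT and 4281 KO peaks. The deposited signal column was the ChIP minus the input reads of a peak, each scaled to 20 M reads of its library. The RPM and signal columns gave library sizes of 58377247 ChIP and 23387459 input reads in WT and 44181910 and 21874452 in KO, with residuals of at most 5.03e-07. Per the file headers, another column held the peak length, which equalled stop minus start. Peaks were present on chromosomes 1 to 19, and other chromosomes were not analysed here. Coordinates are printed as the files give them, and whether the first base counts from 0 or 1 is not stated there. Peak heights depend on how far reads were extended, which the sources used here do not give for either library, so heights of the 2 lists may differ by a common factor.

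The WT library was 1.32 times as deep as the KO library. A median peak held 247 ChIP and 28 input reads in WT, and 167 and 21 in KO. Each genotype had 1 sample, so no test across samples could be made. Peaks and regions are not replicates, so intervals (exact Clopper-Pearson, 95%) cover counting error only, and reads without molecular identifiers are not independent molecules. An interval for a ratio of 2 numbers of peaks was made from the exact binomial interval of their share.

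Peaks were compared by overlap of at least 1 bp. The overlap routine was checked against bedtools 2.31.1 on both lists, with no difference, and tested on simulated data made from the WT list, where it recovered 200 of 200 removed and 380 of 380 added peaks. The chance overlap came from 100 seeded random placements of the other list along the same chromosomes, and the chance distance from 100 placements of the list asked about. Overlapping peaks of both lists were merged into regions, assigned by midpoint to windows of 1 Mb, and the variance of genotype-specific regions over windows was compared with 100 random reassignments, in windows with at least 5 expected regions. Windows were also ordered by their number of merged regions and divided into 5 classes of 467 windows, a comparison added after the data were seen. Peaks shared one to one overlapped a single peak in each direction, reciprocally by at least 50%. A pseudocount of 0.5 reads was added to input reads for the median folds of peak classes and for log ratios of input, and none for the folds of named peaks. Calculations were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots with matplotlib 3.10.9.

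The comparisons, the rule for named regions and the first set of alternatives were fixed before the data were examined, except that the column for the stricter threshold was left open between height and significance and was set to height afterwards. By that rule, named regions were the 4 windows of 1 Mb with the largest KO-only excess, the 4 with the largest WT-only excess, and the 3 widest peaks of each genotype-specific class. The stricter threshold was the median WT height, 0.822 RPM, in both lists. Alternatives were that threshold on both lists or only on the peaks asked about, joining of peaks within 1 kb, an overlap of 50% of the peak, a tolerance of 1 kb, equal list lengths and windows of 5 Mb. Alternatives added after the data were seen were thinning of the WT reads within called peaks to the KO library sizes with the p-value recomputed, scaling of KO heights by the median one-to-one ratio of 0.852, a p-value threshold at the WT median, a raised input, the removal of peaks over 10 kb and a count of regions merged over both lists. The planned comparisons of genes, 18 gene lists, gene locations and peak sequence were not made, because they need an annotation or genome on mm9 and the gene table used here is on GRCm38. For the same reason the Lsh locus was not examined, so the genotype labels have no check from the targeted gene.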

Results

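Monomethylation of lysine 4 of histone H3 (H3K4me1), a mark found at active and primed enhancers, was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in primary mouse embryonic fibroblasts. The fibroblasts came from mid-gestation embryos of the C57BL/6 strain, were used at passage 3 to 4, and were either wild type (WT) or knockout (KO) for Lsh. Lsh, also called Hells, is a chromatin remodeller of the SNF2 family that is needed for normal DNA methylation. Each genotype had 1 H3K4me1 library and 1 input library, so no difference below has a replicate check, and intervals (exact, 95%) cover counting error only. The H3K4me1 libraries held 58377247 reads in WT and 44181910 in KO, and the inputs 23387459 and 21874452. The series also holds bisulfite sequencing of WT fibroblasts, KO fibroblasts and an embryonic stem cell line, which was not analysed here. The comparison of the peak lists shows where calls of H3K4me1 peaks differ between the WT and KO samples. Each list holds reads only at its own peaks. The signal of 1 genotype at peaks called only in the other was thus not measured, and may lie just below the calling limit.

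The full KO list held more H3K4me1 peaks than the full WT list, and KO peaks were shorter and lower. There were 64874 KO and 57298 WT peaks, a ratio of 1.13 (95% interval 1.12 to 1.15). The highest window held at least 12 extended reads in each WT peak and 10 in each KO peak, in libraries of unlike depth. Peaks covered 159 Mb of chromosomes 1 to 19 in KO and 172 Mb in WT, a ratio of 0.921. The median peak length was 2015 bp in KO (quartiles 1461 and 2898 bp) and 2447 bp in WT (quartiles 1729 and 3583 bp). The median peak height, the highest window count of a peak scaled by the size of its library (RPM), was 0.702 in KO and 0.822 in WT. Peaks held 34.5% of the KO and 37.1% of the WT ChIP reads, against 7.86% and 8.69% of the input reads. The mean input-subtracted signal per Mb of peak was 1.02 times as high in KO as in WT. Tall peaks went the other way from the total: 22116 KO and 28777 WT peaks reached the median WT height, a ratio of 0.769 (0.755 to 0.782), and 1443 KO and 6189 WT peaks reached 1.5 RPM, a ratio of 0.233. After KO heights were scaled to a common median at peaks shared one to one, the ratio was 1.17 at the median WT height and 0.667 (0.641 to 0.693) at 1.5 RPM. With a p-value threshold at the WT median in both lists, 29151 KO and 28649 WT peaks remained, a ratio of 1.02.

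Most H3K4me1 sites were present in both genotypes, and those found in 1 genotype were mostly low peaks. Of the KO peaks, 72.4% overlapped a WT peak by at least 1 bp, against a mean of 12.2% when WT peaks were placed at random along the same chromosomes 100 times. Of the WT peaks, 78.3% overlapped a KO peak, against 13.6% at random. The remaining 17873 KO-only peaks made up 27.6% of the KO list (27.2 to 27.9%), and the 12433 WT-only peaks made up 21.7% of the WT list (21.4 to 22.0%). KO-only peaks covered 30.1 Mb and WT-only peaks 24.8 Mb. The median height of KO-only peaks was 0.543 RPM (quartiles 0.453 and 0.656), against 0.792 in shared KO peaks. The median height of WT-only peaks was 0.5995 RPM (quartiles 0.497 and 0.719), against 0.908 in shared WT peaks. KO-only peaks held a median of 103 ChIP and 13 input reads, and WT-only peaks 155 and 19. Median input coverage was 0.380 RPM per kb in KO-only peaks and 0.496 in shared KO peaks, while it was 0.459 in WT-only and 0.495 in shared WT peaks. Among peaks at or above the median WT height, 6.30% of KO peaks (5.98 to 6.63%) and 6.16% of WT peaks (5.89 to 6.45%) had no partner in the full list of the other genotype. The KO share at this threshold was 10.1% after KO heights were scaled to the median of shared peaks, and with a p-value threshold in place of height the shares were 8.21% in KO and 5.49% in WT. Among peaks at or above 1.5 RPM, no partner in the full list of the other genotype was found for 107 of 1443 KO peaks (7.42%, interval 6.12 to 8.89%) and 55 of 6189 WT peaks (0.889%, interval 0.670 to 1.16%). WT reads at these 107 KO peaks were not analysed here, so peaks absent from the WT list alone stay possible. When the threshold at the median WT height was applied to both lists the order turned, with 18.1% KO-only and 39.0% WT-only peaks, and it also turned with lists of equal length, with 22.3% and 25.2%.

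**Figure D1:**
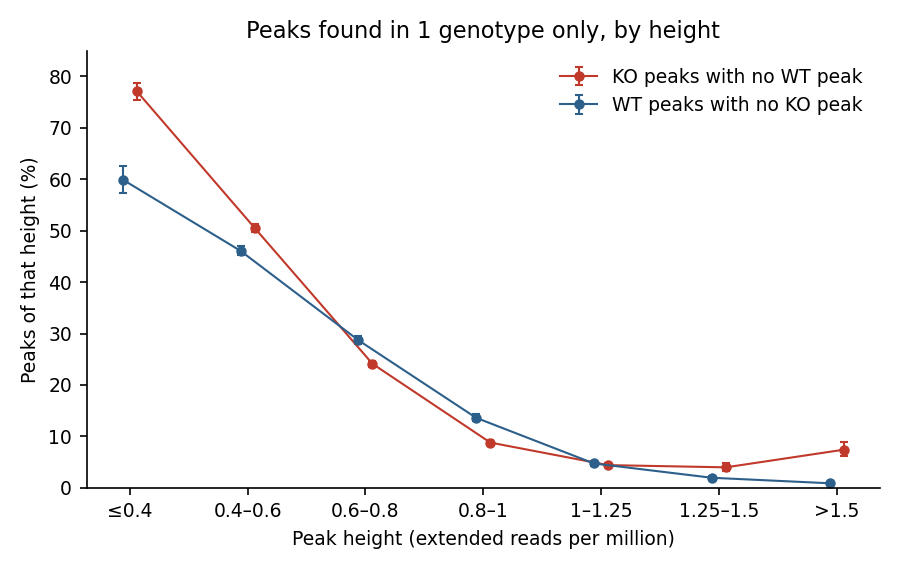
Share of peaks with no overlapping peak in the other genotype (vertical axis, percent) in classes of peak height (horizontal axis, RPM), for KO peaks (red) and WT peaks (blue), with exact 95% binomial intervals. The KO share fell from 77.1% in the lowest class to 3.99% in the class below 1.5 RPM and was 7.42% above 1.5 RPM, where the WT share was 0.889%.

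KO-only H3K4me1 peaks lay farther from WT peaks than WT-only peaks lay from KO peaks. The median distance to the nearest peak of the other list was 11596 bp for KO-only and 6450 bp for WT-only peaks. Of the KO-only peaks, 3439 (19.2%, interval 18.7 to 19.8%) were more than 50 kb from any WT peak. Of the WT-only peaks, 681 (5.48%, interval 5.08 to 5.89%) were more than 50 kb from any KO peak. At more than 200 kb the shares were 5.15% and 0.177%. Randomly placed KO peaks without overlap were more than 50 kb from a WT peak in 41.2% of cases on average, and randomly placed WT peaks were more than 50 kb from a KO peak in 32.6%. KO-only peaks over 50 kb from a WT peak had a median height of 0.521 RPM, a median ChIP to input fold of 4.36 and a median input coverage of 0.338 RPM per kb. Among peaks at or above the median WT height, 10.9% of KO-only peaks (9.32 to 12.7%) and 3.38% of WT-only peaks (2.59 to 4.33%) were more than 50 kb from the full list of the other genotype. With both lists restricted to such peaks the shares were close, 25.9% and 22.2%. At or above 1.5 RPM, 1 of 107 KO-only and 0 of 55 WT-only peaks were that far from the full list of the other genotype.

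**Figure D2:**
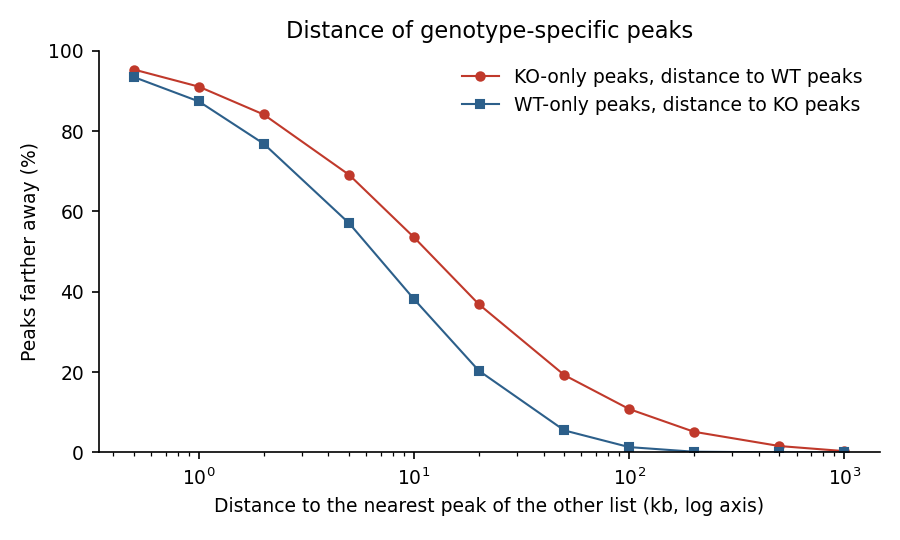
Percent of KO-only peaks (red circles) and WT-only peaks (blue squares) that lie farther than a given distance (horizontal axis, kb, log scale) from the nearest peak of the other genotype. Beyond 100 kb the KO-only share was 10.8% and the WT-only share 1.33%.

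The larger peak number in the full KO list was seen on each of the 19 chromosomes analysed, to different extents. Chromosome 3 had the largest ratio, with 4226 KO and 3445 WT peaks (1.23, interval 1.17 to 1.28). Chromosome 16 came next with 2573 KO and 2168 WT peaks (1.19, interval 1.12 to 1.26). The smallest ratio was on chromosome 17, with 2370 KO and 2256 WT peaks (1.05, interval 0.991 to 1.11), followed by chromosome 11 at 1.06 and chromosome 7 at 1.07. KO-only peaks made up 32.2% of KO peaks on chromosome 3 (30.8 to 33.6%) and 23.6% on chromosome 17 (21.9 to 25.4%). WT-only peaks made up 19.8% of WT peaks on chromosome 3 and 24.7% on chromosome 17. With all peaks of both lists, the KO-only share was above the WT-only share on 18 of 19 chromosomes, chromosome 17 being the exception, and the intervals were apart on 16. KO-only peaks over 50 kb from the other list outnumbered the matching WT-only peaks on 19 of 19 chromosomes, for example 309 against 31 on chromosome 3. Input reads per bp of peak, KO over WT, lay between 0.957 and 1.01 on all 19 chromosomes. This input ratio was lowest on chromosome 3 (0.957), followed by chromosome 16 (0.969). It was highest on chromosomes 11 (1.01) and 7 (1.01), followed by chromosome 17 (0.996). On these chromosomes input in peaks was thus lower where the excess of KO peaks was larger, and the link was not tested. The ratio was taken over each list's own peaks. Median input was lower in KO-only peaks than in shared KO peaks (0.380 against 0.496 RPM per kb). A larger KO-only share can thus lower the ratio by itself. Among peaks at or above the median WT height the ratio of peak numbers turned to 0.773 on chromosome 3 and 0.757 on chromosome 17.

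**Figure D3:**
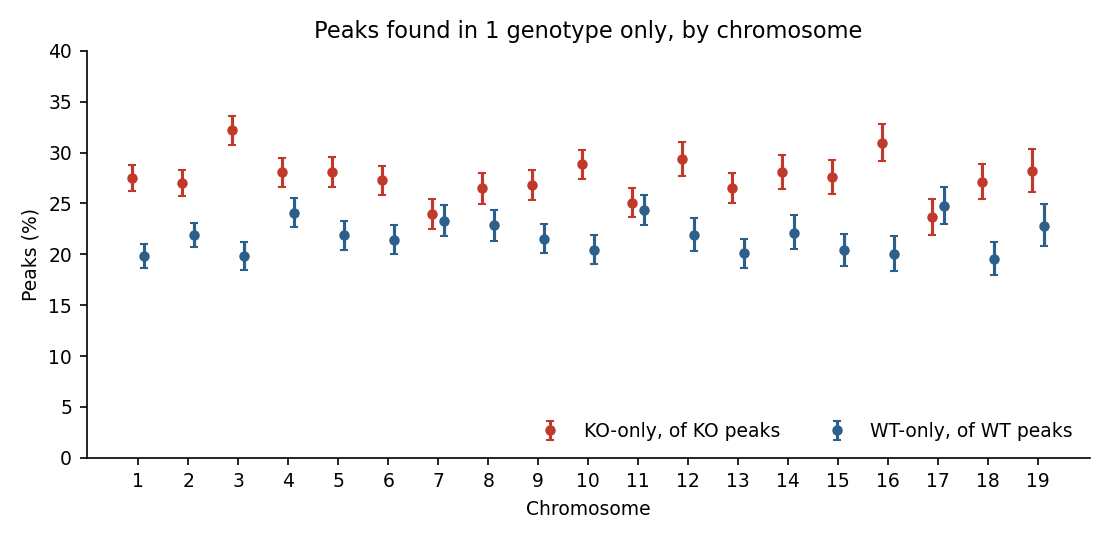
Percent of KO peaks that are KO-only (red) and of WT peaks that are WT-only (blue) on chromosomes 1 to 19, with exact 95% binomial intervals. The KO-only share was highest on chromosome 3 (32.2%) and lowest on chromosome 17 (23.6%), where the WT-only share was 24.7%.

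Peaks of 1 genotype were clustered along the chromosomes when all peaks were used. After overlapping peaks of both lists were merged, 73251 regions remained, of which 42945 (58.6%) were found in both genotypes, 17873 (24.4%) in KO only and 12433 (16.97%) in WT only. The variance of the KO-only count over 1546 windows of 1 Mb was 3.45 times the binomial value, against at most 1.06 in 100 random reassignments of the regions. For WT-only regions it was 2.33 times, against at most 1.10. With both lists restricted to peaks at or above the median WT height, the KO-only value was 1.63 in 53 windows, below the random maximum of 1.69, and the WT-only value was 1.39, against at most 1.11. KO-only peaks outnumbered WT-only peaks in 1550 of 2335 windows, and WT-only peaks outnumbered KO-only peaks in 661.

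The window with the largest KO-only excess was chromosome 4, 64000001 to 65000000 (mm9), with 85 KO peaks, 49 WT peaks, 35 KO-only peaks and 0 WT-only peaks. Its KO-only peaks lay among shared peaks, covered 65.6 kb and had a median height of 0.588 RPM. Chromosome 10, 32000001 to 33000000, held 28 KO and 2 WT peaks, and 20 of its 26 KO-only peaks were more than 50 kb from any WT peak. Chromosome 3, 60000001 to 61000000, held 26 KO-only and 1 WT-only peaks among 60 KO and 35 WT peaks. Chromosome 14, 74000001 to 75000000, held 26 KO-only and 2 WT-only peaks among 58 and 37. On the WT side, chromosome 16, 93000001 to 94000000, held 24 WT-only and 5 KO-only peaks. Chromosome 13, 56000001 to 57000000, held 21 and 3, chromosome 17, 29000001 to 30000000, held 23 and 5, and chromosome 19, 56000001 to 57000000, held 22 and 4. Of the KO-only peaks in the 4 windows with the largest KO excess, 2, 2, 0 and 1 reached the median WT height, in the order given. In the 4 WT windows, 5, 2, 3 and 6 WT-only peaks did, in the order given. The genes in these windows are not reported, since no gene annotation on mm9 was used here.

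**Figure D4:**
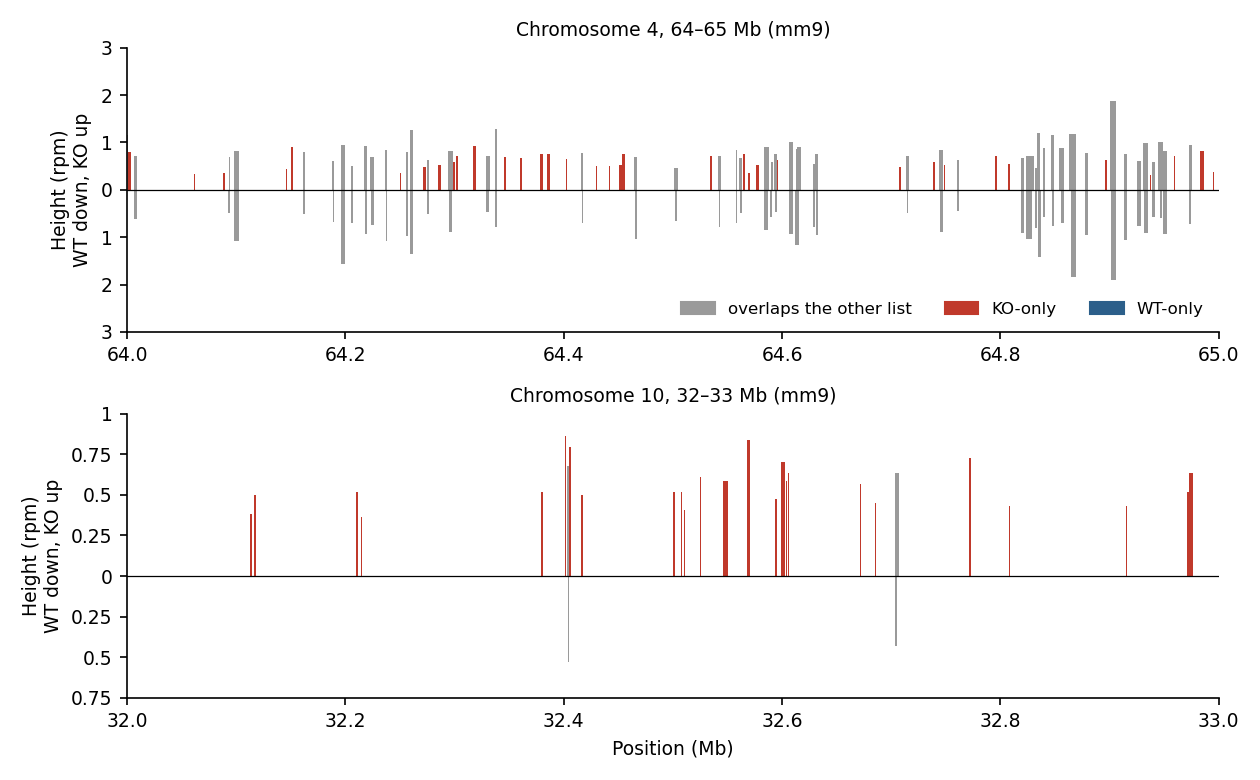
Peaks of KO (upward) and WT (downward) in the chromosome 4 and chromosome 10 windows (mm9), drawn to scale along the chromosome (Mb), with height in RPM. Peaks that overlap the other list are grey and KO-only peaks red, 35 in the chromosome 4 window and 26 in the chromosome 10 window, and neither window holds a WT-only peak.

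KO-only regions made up the largest share of regions where H3K4me1 regions of either genotype were sparse, although their number was lowest there. This comparison was added after the data were seen. In the 467 windows of 1 Mb with the fewest merged regions (1 to 13 per window), 1644 of 2870 regions were KO-only (57.3%, interval 55.4 to 59.1%) and 221 were WT-only (7.70%, interval 6.75 to 8.74%). In the 467 windows with the most regions (49 to 104), 4754 of 27861 were KO-only (17.1%, interval 16.6 to 17.5%) and 5143 WT-only (18.5%, interval 18.01 to 18.9%). The ratio of KO-only to WT-only regions thus ran from 7.44 (6.46 to 8.60) to 0.924 (0.888 to 0.962). Among regions at or above the median WT height it ran from 2.56 (1.59 to 4.24) to 0.570 (0.506 to 0.641).

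**Figure D5:**
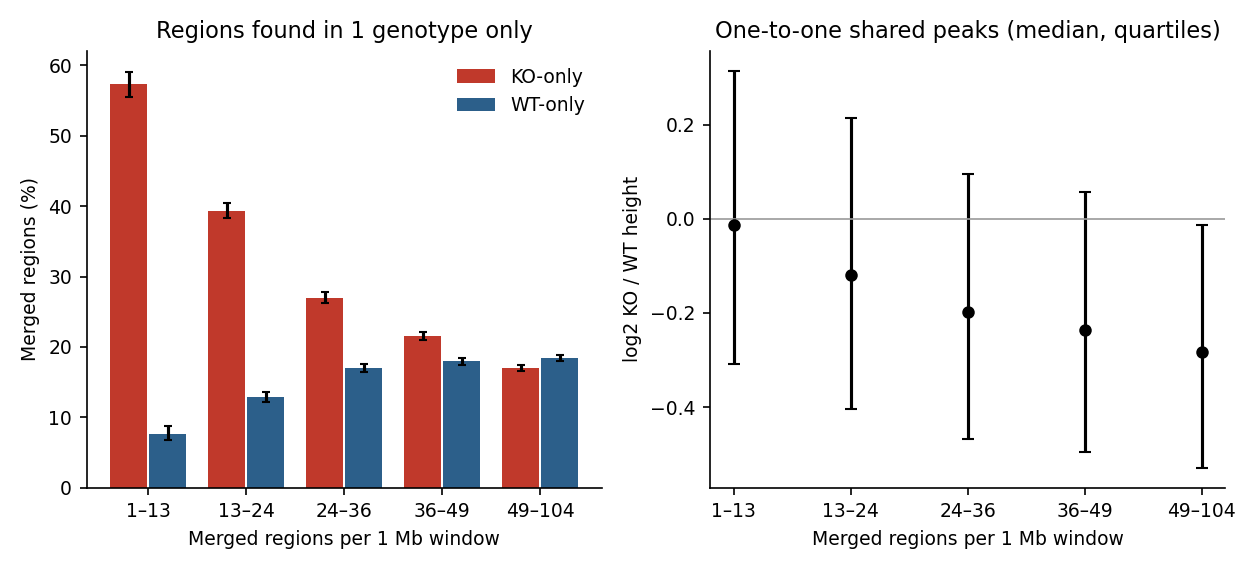
Left, percent of merged regions found in KO only (red) or WT only (blue) in 5 equal classes of 1 Mb windows ordered by their number of regions, with exact 95% binomial intervals. Right, log2 KO over WT height of one-to-one shared peaks in the same classes, as medians with quartiles, which ran from -0.01 in the windows with the fewest regions to -0.28 in those with the most.

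At 34464 peaks shared one to one, with a reciprocal overlap of at least 50%, heights were lower in KO and total signal was close to equal. The median log2 KO over WT height was -0.23 (quartiles -0.49 and 0.06), and 29.3% of pairs were higher in KO. KO height was at least 2-fold lower in 695 pairs and at least 2-fold higher in 154, while input-subtracted reads were lower by that much in 1279 and higher in 1481, and ChIP RPM per kb in 17 and 133. The median log2 ratio of input-subtracted reads was -0.05, that of ChIP RPM per kb was 0.08, and that of peak length was -0.13, so the sign depended on the measure. The median log2 height ratio rose from -0.28 in the windows with the most regions to -0.01 in those with the fewest, while the matching input ratio stayed between 0.01 and 0.03 in all 5 classes of windows.

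The widest H3K4me1 domains were usually shared, with more exceptions in KO. Of 399 KO peaks over 10 kb, 42 had no WT peak (10.5%, interval 7.69 to 14.0%), and of 872 WT peaks over 10 kb, 12 had no KO peak (1.38%, interval 0.713 to 2.39%). The widest KO-only peak was at chromosome 4, 138777901 to 138819799, with a length of 41898 bp, 6549 ChIP reads, 591 input reads and a height of 1.92 RPM, 472 bp from a WT peak. The next were at chromosome 11, 117161316 to 117189677, with 5883 ChIP reads and a height of 2.38 RPM, and at chromosome 5, 144423241 to 144446438, with 3643 ChIP reads and a height of 1.74 RPM, at 6513 and 3576 bp from a WT peak. The widest WT-only peak was at chromosome 1, 43183936 to 43212414, with 5943 ChIP reads, a length of 28478 bp, 345 input reads and a height of 2.36 RPM, 5846 bp from a KO peak. It was followed by chromosome 1, 73974274 to 73991539, with 2582 ChIP reads, and chromosome 17, 79736055 to 79751798, with 3045. These 6 peaks had ChIP to input folds between 4.64 and 7.26.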

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

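The alternatives of thinning, height scaling, the p-value threshold, the raised input, the removal of wide peaks and the count of merged regions were chosen after seeing the data. Autosomes alone were not run because both lists hold chromosomes 1 to 19 alone, and the alternatives for genes, locations and sequence were not run for lack of mm9 annotation. No paired analysis was possible because each genotype had 1 sample with no replicate number, and for the same reason no replicate could be left out. The KO over WT ratio of peak number, 1.13, reversed to 0.769 with the stricter threshold on both lists, and so did the ratios on chromosome 3 (0.773) and chromosome 17 (0.757). Scaling of KO heights to the median of shared peaks brought the total at that threshold to 1.17, and the cause of the shifts on single chromosomes was not tested. The ratio was 1.15 with peaks within 1 kb joined, 1.10 with regions merged over both lists, 1.21 with WT thinned to the KO library sizes and 1.02 with the p-value threshold. Thinning was applied only within called WT peaks, so it could remove WT peaks but not KO peaks. It could thus only raise this ratio, the ratio of covered length and the KO-only share of KO peaks. The KO over WT ratio of covered length, 0.921, stayed below 1, at 0.700 with the threshold on both lists, 0.956 after thinning, 0.939 after height scaling and 0.864 with the p-value threshold. The share of KO peaks found in KO only, 27.6%, was 18.1% with the threshold on both lists, 6.30% with it on the peaks asked about, 29.5% with 50% of the peak covered, 25.1% with a 1 kb tolerance, 22.3% with equal list lengths, 30.2% after thinning, 10.1% after height scaling, 8.21% with the p-value threshold and 20.2% with raised input. The share of WT peaks found in WT only, 21.7%, was 39.0%, 6.16%, 27.1%, 18.96%, 25.2%, 19.6%, 5.49% and 17.95% under the same alternatives in the same order, height scaling left out. The KO-only share was thus below the WT-only share with the threshold on both lists and with equal list lengths. The share of KO-only peaks over 50 kb from a WT peak, 19.2%, was 25.9%, 10.9%, 17.9%, 21.1%, 17.8%, 20.4%, 14.4%, 16.9% and 16.9% in the order of the KO list of alternatives. The matching share of WT-only peaks, 5.48%, was 22.2%, 3.38%, 4.38%, 6.27%, 7.01%, 3.37% and 4.73%, with thinning (5.32%) and height scaling left out of that order, and was below the KO-only share under each of these. Removal of peaks over 10 kb moved none of the 4 shares beyond its interval. The variance ratio of KO-only regions over windows, 3.45, was 8.78 in windows of 5 Mb and 1.63 with the threshold on both lists, where only 53 windows could be used and random reassignments reached 1.69. That of WT-only regions, 2.33, was 3.85 and 1.39. Depth limits the comparison at low peaks, where a median of 103 ChIP reads stood behind a KO-only peak.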

Other observations

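The tests of input coverage between genotypes, of the height scale and of wide peaks were chosen after the results they measure were seen. Relative to the common shift of -0.23 in log2 height at one-to-one shared peaks, H3K4me1 in KO fibroblasts was higher at sites in sparse parts of the genome and lower at sites in dense parts. The median log2 height ratio was -0.01 in the 467 windows with the fewest regions (812 pairs), -0.12, -0.20 and -0.24 in the next 3 classes, and -0.28 in the 467 windows with the most (14135 pairs). ChIP RPM per kb gave the same order, with medians from 0.28 to 0.04. The class with the fewest regions had the higher median height ratio on 19 of 19 chromosomes. All values are relative to library totals, so a gain at sparse sites cannot be separated from a loss at dense ones.

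A hypothesis is that loss of Lsh may raise H3K4me1, relative to the rest of the genome, across parts that carry few such sites. It predicted a higher KO over WT height at shared peaks there, and the outer classes differed by 0.27 on the log2 scale. These heights come from the same libraries and windows as the KO-only calls. Any difference between the libraries that yields KO-only calls there could also shift them, so the result is not independent support. Peaks below the median WT height do not account for all of the pattern. Among regions at or above that height the KO-only share was 3.58 times as high in the sparse as in the dense class. Heights of these regions were not matched between the classes. The share of such KO-only peaks over 50 kb away was 3.23 times the WT-only share against full lists. With both lists restricted it was only 25.9% against 22.2%. At or above 1.5 RPM the distance pattern was not seen, with 1 of 107 KO-only and 0 of 55 WT-only peaks over 50 kb away. Selection of weak shared peaks is not most of the difference in height ratio, which was 0.22 (jackknife SE over chromosomes 0.017) in pairs matched on mean height. That SE measures spread over chromosomes of the same libraries and not between libraries. Low input may give part of the pattern but not all of it. With input raised to the median density of shared peaks, 1918 of 11335 KO-only peaks (16.9%) were over 50 kb away. Without it the number was 3439 of 17873 (19.2%). The log2 KO over WT input density of shared pairs differed between the outer classes by -0.0073, against 0.27 for height. That value covers sites called in both lists and cannot decide on input at KO-only peaks. A GC bias that differs between the ChIP libraries and a difference between the cultures other than genotype stay open, as each genotype had 1 library and no mm9 sequence was used.

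The KO list had more peaks in all but fewer tall ones. Splitting of broad regions does not account for all of the larger number, since the KO over WT ratio of 1.13 was 1.15 after peaks within 1 kb of each list were joined. A part may come from it, as the ratio was 1.10 when regions merged over both lists were counted, where long WT peaks can also bridge separate KO peaks, and 6.33% of WT peaks overlapped at least 2 KO peaks against 2.82% of KO peaks that overlapped at least 2 WT peaks. A common factor on all KO heights may account for part of the missing tallest peaks but not all, since scaling by the median of shared pairs brought the ratio at 1.5 RPM from 0.233 to 0.667. What lowered the rest stays open, and ChIP RPM per kb at shared pairs went the other way from height (median log2 0.08).

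The KO-only share rose again among the widest peaks, from 5.16% between 5 and 10 kb to 10.5% above 10 kb in length. The WT-only share did not rise, at 3.14% between 5 and 10 kb and 1.38% above. This cannot exclude a loss of wide peaks by the caller in both lists. Only 399 KO but 872 WT peaks were over 10 kb. Many wide WT peaks can thus have shorter KO partners, which such a loss would leave in place. Wide peaks lost from both lists or from the WT list alone, and broad domains gained in KO, may each give this pattern. All stay open, as WT reads in these intervals were not analysed here.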
